A study of Mus musculus with 12 samples.

How the data were processed

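Polyadenylated RNA of mouse embryonic stem cells of the line V6.5 was measured by single-end RNA sequencing in 12 libraries, 3 in each of 4 groups. The cells were grown for 5 passages in medium with serum and leukemia inhibitory factor (serum/LIF), with or without a pair of kinase inhibitors against MEK and GSK3b known together as 2i. They then received 500 nM JQ1 or vehicle for 72 h. JQ1 is a small molecule that occupies the bromodomains of the BET proteins Brd2, Brd3, Brd4 and Brdt and displaces them from acetylated chromatin. The serum/LIF medium with the inhibitors is called 2i here.

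Per the labels, the authors used bcl2fastq 2.17, TopHat, HTSeq and edgeR with the mouse build mm9. The annotation, the counting mode and the definition of the library size are not stated, so no gene coordinates are printed. The deposited table gives CPM, read counts scaled to the size of the library, for 24468 genes. All values (100% within a tolerance of 1e-06 of a whole multiple) were whole read counts times 1 constant per library, so the reads could be recovered. The columns sum to between 309000 and 374000 CPM, and to 881440 CPM in 2i vehicle replicate 2, so the library size behind the deposited CPM was larger than the reads of the listed genes. The CPM printed here are the deposited ones, and their median column total is 353921 CPM. They are relative to the library size, so rises and falls are relative too, and a shift of all genes alike cannot be seen. The kit made unstranded libraries, so reads of overlapping genes on opposite strands cannot be assigned with certainty. Counts of near-identical copies, such as the Zscan4, Tcstv, Rhox and histone genes, are uncertain for the same kind of reason. Tdg and Hmgcs1 lay below the filter, and no mitochondrially encoded gene was in the table.

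The reads of the listed genes numbered between 24545942 and 72755364 per library. In 2i vehicle replicate 2, the ribosomal RNA precursor Rn45s took 56.2% of the reads, 18854126 of 33535816. Where a group held 0 reads of a gene, a fold is given as a bound against 3 reads over the group. Such bounds cover counting error only, because reads without molecular identifiers are not independent molecules.

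Genes with at least 0.354 CPM in at least 3 of the 12 libraries were tested, which kept 13665 genes and left out 10803. The log2 of CPM plus 0.177 was fitted in R 4.3.3 with limma 3.58.1, with a mean for each group and a trended, robust empirical Bayes estimate of the spread. The 5 contrasts were the effect of JQ1 in each medium, the difference between those effects, and the effect of 2i with vehicle and with JQ1. Where a group lies below the added 0.177 CPM, the pseudocount, a log2 value depends on that choice. A gene is called changed at a Benjamini-Hochberg adjusted p below 0.05 within a contrast. These p-values measure only the spread between the libraries, which may be technical, since the labels do not say how the replicates were made. For the difference between the JQ1 effects, "rose" or "higher" means a larger log2 fold change in 2i than in serum/LIF.

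The groups, contrasts, tests, alternatives, 30 gene lists and the rule for naming genes were fixed before the data were examined. Of the lists, 29 had measured members. Each list was compared with all other genes by limma's camera with a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a contrast, and again with a correlation estimated per list. No list call in any of the 5 contrasts held with the estimated correlation. For each contrast, the rule named the 8 genes that rose and the 8 that fell most, among genes with at least 1.77 CPM in the higher group and, for pairs of groups, no overlap between their libraries. It added up to 4 members of each list with the smallest adjusted p and a fixed set of pluripotency, DNA methylation and BET genes. The absence of overlap between 3 libraries and 3 others arises by chance in 10% of genes.

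The procedure was tested on simulated data with 13039 genes. In the serum/LIF contrast it called 55.1% of genes simulated at a fold of 1.25, 89.6% at 1.5, 93.6% at 2 and 100% at 4, and 8 of 12846 unchanged genes. For the difference between the JQ1 effects the shares were 26.5%, 72.9%, 87.2% and 100%, with 11 of 12846 unchanged genes called. A list of 20 risen genes was called and 0 of 28 random lists were. The simulation changed few genes, only in serum/LIF with JQ1 and in both directions, with no shift of scale and no outlying library. In the real data most genes changed and some libraries stood apart, so these shares do not carry over to them as error rates.

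The alternatives were median-of-ratios size factors, quantile normalization, other pseudocounts and filters, fits to the groups of a contrast alone, sample quality weights, a term for the replicate number, each library left out in turn, and edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads. A fit without serum/LIF vehicle replicate 2 and 2i vehicle replicate 2 was added after seeing the data. The replicate number was not used to pair libraries in the main contrasts, because the labels state no pairing.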

Results

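RNA sequencing measured 24468 genes in 12 libraries of V6.5 mouse embryonic stem cells, 3 each from serum/LIF with vehicle, serum/LIF with JQ1, 2i with vehicle and 2i with JQ1. The libraries held 24545942 to 72755364 reads of the listed genes. The groups lay apart on the first principal components, which held 56.9% and 31.5% of the variance. All values below are means of CPM ± SD with n = 3 unless stated, and errors of log2 fold changes are standard errors.

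A pair of libraries stood apart from the other members of their groups. Serum/LIF vehicle replicate 2 held 118 CPM of the macrophage lysozyme gene Lyz2, against 2.36 and 2.48 in replicates 1 and 3, and 132 summed CPM of 28 other macrophage genes, against 37.1 and 40.8. That library also held 2346 CPM of the ribosomal precursor Rn45s, against 324.5 and 358.8 in replicates 1 and 3. In 2i vehicle replicate 2 Rn45s reached 495550 CPM. There 69 histone genes summed to 594 CPM, against 9.66 and 9.03 in replicates 1 and 3. Without both libraries, 3707 of the 3775 genes with an absolute log2 fold change of at least 1 for JQ1 in serum/LIF remained so, and 2288 of 2391 in 2i. The same held for 2842 of 2987 genes for the difference between these effects and 3326 of 3457 for 2i with vehicle.

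**Figure D1:**
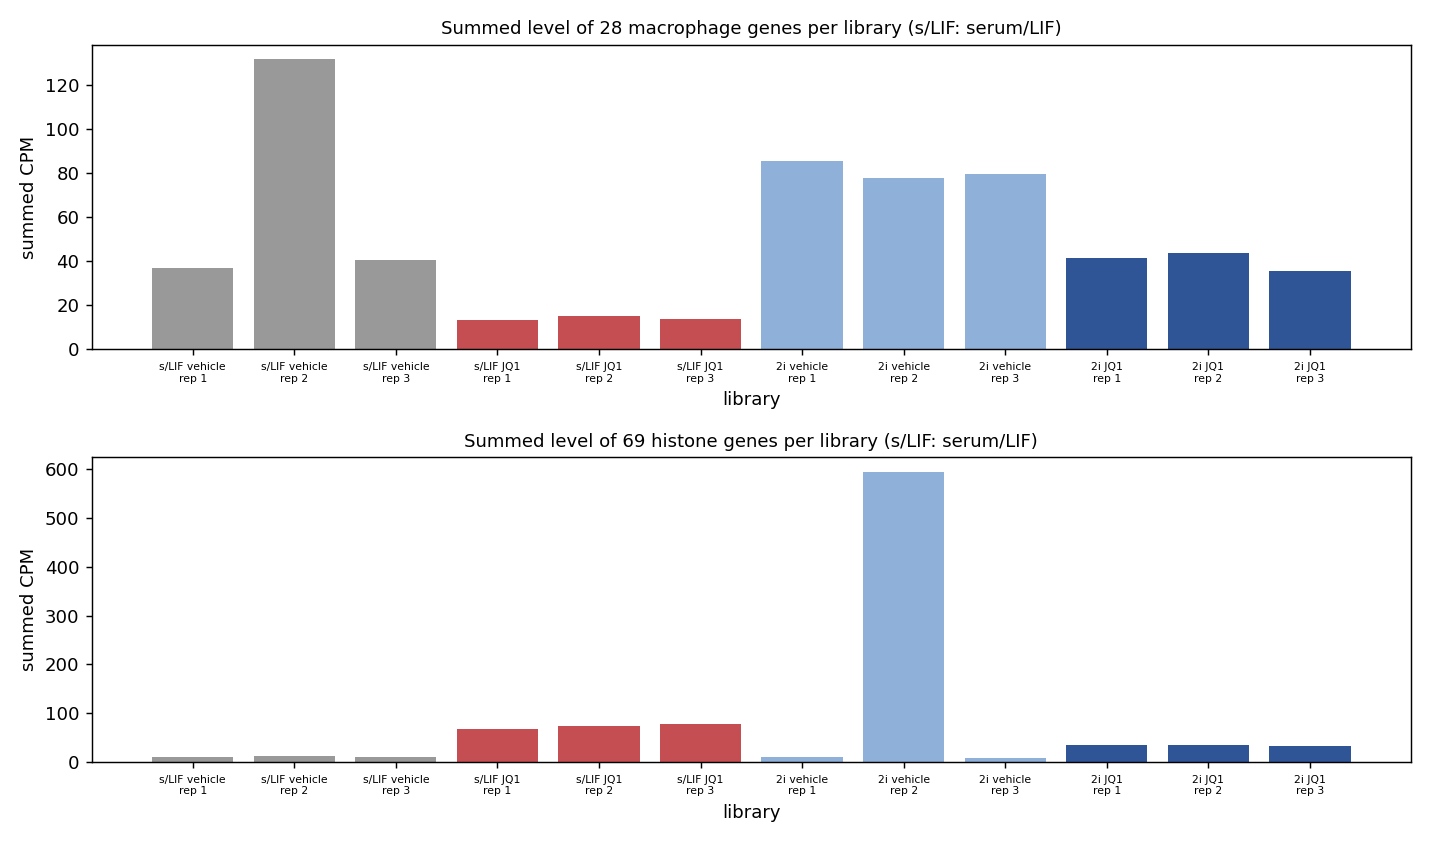
Summed CPM of 28 macrophage genes (upper panel) and 69 histone genes (lower panel) in each of the 12 libraries, coloured by group. Serum/LIF vehicle replicate 2 reaches 132 in the upper panel and 2i vehicle replicate 2 reaches 594 in the lower. The 2i vehicle libraries stand between 77.75 and 85.55 in the upper panel.

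The effect of JQ1 in serum/LIF asks what the compound does to stem cells in a medium that permits differentiation. Most of the listed pluripotency genes fell. Nanog fell from 138 ± 6.36 to 8.4 ± 1.12 CPM, a log2 fold change of -4.02 (SE 0.07), and Pou5f1, which encodes Oct4, fell from 317 ± 8.58 to 24.9 ± 1.09 CPM. Prdm14, a repressor of differentiation, fell from 8.6 ± 0.634 to 0.0191 ± 0.0101 CPM, and Esrrb from 167 ± 10.8 to 18.7 ± 1.28 CPM. The filamin gene Flnc rose from 33.4 ± 0.467 to 764 ± 39.8 CPM.

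Of the 18 naive pluripotency genes, 14 fell and 3 rose, with a median log2 fold change of -3.20 (camera, Benjamini-Hochberg adjusted p = 2.67e-04, and adjusted p = 0.164 with an estimated correlation). Pecam1 fell by 5.06 on the log2 scale, the nuclear receptor gene Nr5a2 by 4.78, and the orphan receptor gene Nr0b1 from 35 ± 2.18 to 0.0725 ± 0.0191 CPM. Among 15 core pluripotency genes 12 fell and 3 rose (camera, Benjamini-Hochberg adjusted p = 0.0195, and adjusted p = 0.312 with an estimated correlation). Fgf4 and Tdgf1, which encode a growth factor and a Nodal co-receptor, had log2 fold changes of -5.48 and -6.71, and Sox2 one of -0.84. Klf4, a LIF-responsive reprogramming factor, fell from 57.8 ± 2.26 to 7.55 ± 0.66 CPM. Formative and primed genes fell as well, 13 of 17 with 4 that rose, among them Foxd3 with a log2 fold change of -3.90 (camera, Benjamini-Hochberg adjusted p = 0.0288, and adjusted p = 0.373 with an estimated correlation). Without the other groups in the fit, that list had a camera, Benjamini-Hochberg adjusted p of 0.055, with a filter of 1.77 CPM one of 0.0818 and by edgeR one of 0.0768.

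The mesendoderm and primitive streak list fell in 9 of 10 members (camera, Benjamini-Hochberg adjusted p = 6.55e-04, and adjusted p = 0.0945 with an estimated correlation). Its members include the Nodal antagonist Lefty1, which fell from 98.6 ± 6.12 to 0.12 ± 0.0214 CPM, the Nodal cofactor Foxh1 and brachyury (T), with log2 fold changes of -3.93 and -4.58. Lefty2, from outside the list, fell from 55.5 ± 1.91 to 0.0127 ± 0.00368 CPM. Markers of later lineages were divided and none of their lists was called, although the endoderm list had a camera, Benjamini-Hochberg adjusted p of 0.0163 upward under quantile normalization and 0.00741 by edgeR. Of 15 endoderm genes 10 rose, among them the basement membrane collagens Col4a1 and Col4a2 with 3.25 and 3.41 on the log2 scale. Of 11 neuroectoderm genes 9 rose, such as Nes, which encodes nestin, from 32.5 ± 3.33 to 218 ± 11.2 CPM, while Olig2 fell. Of 13 mesoderm and smooth muscle genes 9 rose and 4 fell, with the smooth muscle actin gene Acta2 at 4.29 ± 0.477 and then 93.8 ± 7.94 CPM and desmin (Des) at a log2 fold change of -3.53.

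The listed matrix and adhesion genes had the lowest adjusted p of all lists, with 17 of 18 higher and 0 lower at a median log2 fold change of 1.49 (camera, Benjamini-Hochberg adjusted p = 7.74e-07, and adjusted p = 0.0945 with an estimated correlation). Collagen genes, a family chosen after the result was seen, were divided, with 12 of 29 higher and 13 lower. Tpm1, a tropomyosin gene, rose from 135 ± 3.45 to 815 ± 27.5 CPM, the YAP target Cyr61 from 31 ± 1.13 to 275 ± 16.1 CPM, and Cald1 and Amotl2 by 2.30 and 2.48 on the log2 scale. The neural cadherin gene Cdh2 rose by 4.21. Cholesterol synthesis genes rose in 17 of 18 members (camera, Benjamini-Hochberg adjusted p = 6.55e-04, and adjusted p = 0.373 with an estimated correlation), such as the receptor gene Ldlr and the enzyme gene Dhcr24 by 1.79 and 1.24. The exception was Pcsk9, which encodes a protein that degrades the Ldlr receptor, with a log2 fold change of -2.86. Of 17 p53 targets and cell cycle inhibitors 10 rose and 4 fell (camera, Benjamini-Hochberg adjusted p = 0.0274, and adjusted p = 0.373 with an estimated correlation). Mdm2 rose by 1.78 and Cdkn2a, the locus of p16 and p19Arf, by 2.90. Under quantile normalization this list had a camera, Benjamini-Hochberg adjusted p of 0.1. The G2/M list fell in 15 of 20 members and rose in 2 (camera, Benjamini-Hochberg adjusted p = 0.0195, and adjusted p = 0.373 with an estimated correlation), with Bub1b and Ccnb1 at -1.06 and -0.92.

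Germline and methylation-sensitive genes fell in 16 of 20 members and rose in 1 (camera, Benjamini-Hochberg adjusted p = 2.81e-04, and adjusted p = 0.0945 with an estimated correlation). The piRNA pathway gene Piwil2 and the meiotic axis gene Sycp3 had log2 fold changes of -4.14 and -4.21. The list of TET dioxygenases and base excision repair fell in 8 of 9 members (camera, Benjamini-Hochberg adjusted p = 0.0195, and adjusted p = 0.108 with an estimated correlation). Tet1, which oxidizes 5-methylcytosine, fell from 221 ± 2.61 to 13.1 ± 0.602 CPM and Tet2 from 21 ± 1.59 to 6.42 ± 0.237 CPM. Tet3 alone of the list rose, from 6.79 ± 0.403 to 39.2 ± 1.03 CPM. The de novo methyltransferase gene Dnmt3a fell from 50.5 ± 4.86 to 5.25 ± 0.0324 CPM, with log2 fold changes of -0.37 for Dnmt3b, -1.02 for Dnmt3l and 0.33 for the maintenance enzyme gene Dnmt1, which had 0.066 and no call under quantile normalization. Interferon-stimulated genes fell in 9 of 11 members (camera, Benjamini-Hochberg adjusted p = 0.00459, and adjusted p = 0.0945 with an estimated correlation), among them Oasl2 and Bst2 with -4.44 and -2.08. Summed macrophage markers were also lower, at 0.204 times the vehicle level and 0.366 times without serum/LIF vehicle replicate 2. Laptm5 alone made up 18.28 of 37.11 CPM of that sum in vehicle replicate 1 and 8.041 of 13.59 CPM in JQ1 replicate 1. The sum also stood between 77.75 and 85.55 CPM in the 2i vehicle libraries. It therefore cannot be read as a measure of macrophage RNA alone. Whether cells other than stem cells contribute was not tested.

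Genes known to rise when BET proteins are blocked did so in 9 of 11 members, with 1 that fell (camera, Benjamini-Hochberg adjusted p = 0.0114, and adjusted p = 0.0945 with an estimated correlation). Hexim1, which encodes an inhibitor of P-TEFb, rose from 19.3 ± 0.517 to 42.5 ± 0.891 CPM and the linker histone gene H1f0 from 30.1 ± 0.487 to 149 ± 5.45 CPM. Brd2 rose from 107 ± 3.46 to 366 ± 10.3 CPM. Brd4 and Brd3 rose by 0.21 and 0.18 on the log2 scale, but had -0.022 and -0.029 under quantile normalization. Brdt did not pass at -0.20, but was called in opposite directions by alternatives, at 0.50 under quantile normalization and at -0.22 with sample quality weights. Myc rose from 13.1 ± 0.872 to 34.2 ± 2.41 CPM, while Mycn fell from 72.4 ± 2.23 to 13.6 ± 0.874 CPM.

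In all, 11426 of 13665 genes changed with JQ1 in serum/LIF, 5542 upward and 5884 downward (limma, Benjamini-Hochberg adjusted p below 0.05). At an absolute log2 fold change of at least 1, 1456 were higher and 2319 lower. The median log2 fold change of all tested genes was -0.0306, and the balance of rises and falls depends on the scaling. Camera called 12 lists, and adjusted over the list alone their counts were the same except for 16 falling G2/M genes.

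**Figure D2:**
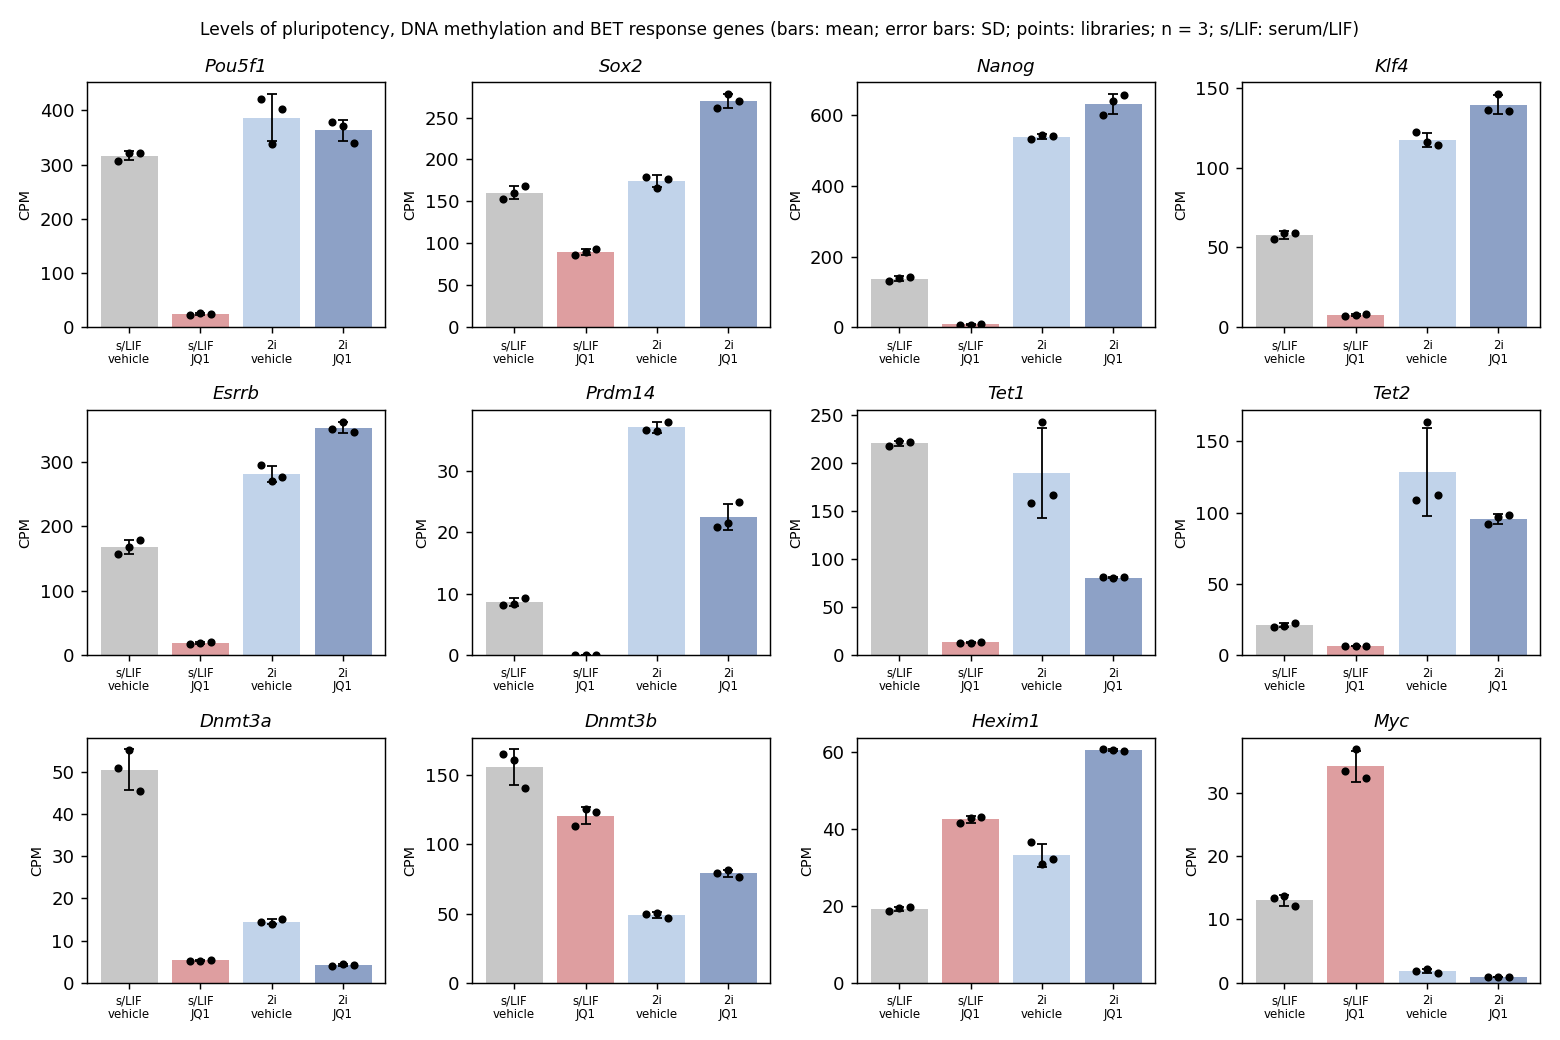
CPM of 12 genes of pluripotency, DNA methylation and the response to BET inhibition in the 4 groups (bars, mean; error bars, SD; points, the 3 libraries of a group). Nanog falls from 138 to 8.4 CPM with JQ1 in serum/LIF and stands at 540 and 633 CPM in 2i.

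The effect of JQ1 in 2i asks whether stem cells held in the naive state respond to BET inhibition in the same way. Nanog was 539.6 ± 6.7 CPM with vehicle and 633 ± 28 with JQ1, Sox2 rose from 174 ± 7.22 to 269 ± 8.59 CPM, and Esrrb rose from 280.4 ± 12.5 to 353 ± 8.26 CPM. Pou5f1 was 386 ± 43.4 and 363 ± 19.9 CPM and did not pass the test, but alternatives called a fall. Its log2 fold change was -0.28 under quantile normalization, -0.14 with sample quality weights and -0.18 without 2i vehicle replicate 2 (limma, Benjamini-Hochberg adjusted p = 0.00109, 0.00261 and 0.00138), and it was -0.16 by both edgeR and DESeq2 (Benjamini-Hochberg adjusted p = 0.0362 and 0.0178). The largest falls were in Lefty2, from 36 ± 2.32 to 0.0846 ± 0.0254 CPM, and in genes such as the epoxide hydrolase gene Ephx2, from 46 ± 1.11 to 0.986 ± 0.194 CPM. The largest rise was in the imprinted noncoding RNA H19, from 1.63 ± 0.356 to 53.9 ± 4.9 CPM, a log2 fold change of 4.92 (SE 0.15).

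The small changes of Nanog and Klf4, 0.23 and 0.25 on the log2 scale, passed the test, but under quantile normalization they were -0.035 and 0.09 and did not. Of 18 naive pluripotency genes 5 rose and 10 fell, and of 15 core genes 5 rose and 5 fell, and neither list was called. Among those that fell, Prdm14 went from 37.1 ± 0.84 to 22.5 ± 2.13 CPM, Nr0b1 from 45.7 ± 4.18 to 14.8 ± 1.35 CPM and Tcl1, a cofactor of Akt, from 30.3 ± 3.38 to 1.95 ± 0.0694 CPM. Tdgf1 and the RNA-binding protein gene Lin28a had log2 fold changes of -1.26 and -1.39. Tet1 fell from 189 ± 46.7 to 80.6 ± 0.897 CPM. Tet2 had a log2 fold change of -0.40 that lost its call without 2i JQ1 replicate 1 (-0.37, limma, Benjamini-Hochberg adjusted p = 0.0563) and stood at -0.21 without 2i vehicle replicate 2. Dnmt3a fell from 14.5 ± 0.513 to 4.16 ± 0.176 CPM, whereas Dnmt3b and Dnmt3l rose by 0.69 and 1.08.

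Trophectoderm genes rose in 9 of 12 members and fell in 0, with a median log2 fold change of 1.23 (camera, Benjamini-Hochberg adjusted p = 0.00703, and adjusted p = 0.45 with an estimated correlation). The keratin genes Krt8 and Krt18 rose from 2.66 ± 0.191 to 20 ± 0.774 and from 2.42 ± 0.202 to 35.4 ± 2.96 CPM, and the imprinted gene Peg10 from 19.7 ± 1.68 to 129 ± 4.38 CPM. The placental regulators Gata2 and Esx1 rose by 3.67 and 2.44 on the log2 scale. The homeobox genes Rhox6 and Rhox9, close copies of each other, rose from 0.434 ± 0.10 to 10.8 ± 0.81 and from 0.432 ± 0.0429 to 9.73 ± 0.718 CPM. The imprinted growth factor gene Igf2 and the Kit ligand gene Kitl rose by 3.5 and 3.74.

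Genes of the 2-cell-like state, in which rare stem cells express transcripts of the cleavage embryo, fell in all 7 members (camera, Benjamini-Hochberg adjusted p = 0.00137, and adjusted p = 0.331 with an estimated correlation). Only 7 of the 19 listed genes were tested. Apart from Eif1a, these had at most 2 reads in any group other than 2i vehicle, so only the 2i vehicle libraries carried them past the filter. The direction of their change was therefore fixed in advance, and the list test cannot support it. Zscan4a had 1.83 ± 0.279 CPM with vehicle and 0 reads in the 3 JQ1 libraries, at least 183-fold lower, and Tcstv1 was at least 124-fold lower. Wnt target genes fell in 9 of 16 members and rose in 4, without a call for the list, which had a camera, Benjamini-Hochberg adjusted p of 0.0266 with a filter of 1.77 CPM and 7.93e-04 by edgeR. Cdx1 fell from 19.9 ± 1.27 to 0.78 ± 0.0604 CPM, Sp5 from 15 ± 2.07 to 0.473 ± 0.0992 CPM and Notum, an inactivator of Wnt proteins, from 34 ± 4.11 to 4.11 ± 0.484 CPM. Germline genes fell in 14 of 20 members, such as Tuba3a with a log2 fold change of -2.82, also without a call. Matrix and adhesion genes were divided, 8 up and 8 down of 18, with the integrin gene Itga5 falling from 23.1 ± 0.963 to 4.38 ± 0.226 CPM.

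BET inhibition markers rose in 7 of 11 members and fell in 3. Txnip, a regulator of thioredoxin and glucose uptake, rose from 38.7 ± 3.52 to 305 ± 4.57 CPM and Hexim1 from 33.2 ± 3.0 to 60.6 ± 0.224 CPM. The list was not called (camera, Benjamini-Hochberg adjusted p = 0.145, and adjusted p = 0.45 with an estimated correlation), but without 2i vehicle replicate 2 its camera, Benjamini-Hochberg adjusted p was 0.0398, and by edgeR 0.0109. Brd2 and Brd4 rose by 0.93 and 0.51. Brd3 had 0.16, but no call at 0.017 under quantile normalization or at 0.086 by edgeR, and Brdt fell by 0.49, with 0.21 under quantile normalization. Myc was low and had a log2 fold change of -0.86, with -0.18 and no call under quantile normalization.

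In all, 10378 genes changed with JQ1 in 2i, 5408 upward and 4970 downward (limma, Benjamini-Hochberg adjusted p below 0.05). At an absolute log2 fold change of at least 1, 485 were higher and 1906 lower. Camera called 2 lists, with the same counts adjusted over the list alone. With a filter of 1.77 CPM the 2-cell-like list kept only Eif1a and could not be tested. The muscle gene Ttn fell in 2i with a log2 fold change of -6.44 (SE 0.35), which was -5.98 without both libraries that stood apart.

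**Figure D3:**
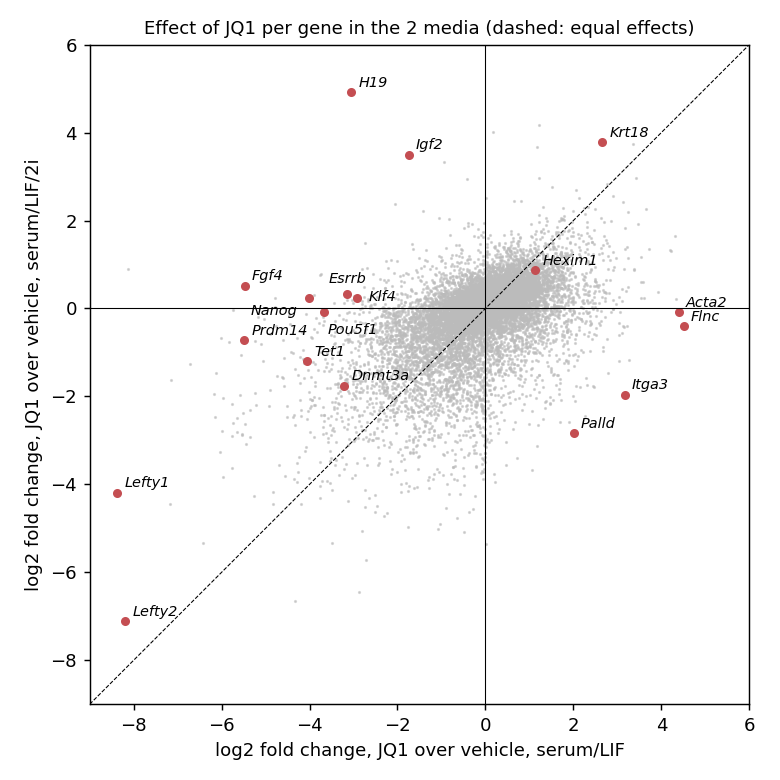
Log2 fold change of each tested gene with JQ1 in serum/LIF (horizontal axis) and in 2i (vertical axis), with named genes in red and equal effects on the dashed line. Across 13665 genes Pearson's r is 0.539, Nanog lies at -4.02 and 0.23, and H19 at -3.06 and 4.92.

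Across 13665 genes, which are not independent replicates, the JQ1 effects in the media had a Pearson's r of 0.539. At an absolute log2 fold change of at least 1, 252 genes were higher in both media and 1029 lower in both, against 52 and 323 for independent effects. There were 81 genes higher in serum/LIF and lower in 2i at that size, and 18 the other way round.

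The difference between the JQ1 effects asks which genes respond to the compound differently in the media, and was tested directly. Nanog, with log2 fold changes of -4.02 in serum/LIF and 0.23 in 2i, differed by 4.25 (SE 0.10), and Pou5f1 by 3.57 (SE 0.09). Fgf4, which fell in serum/LIF, rose from 132 ± 1.18 to 188 ± 5.87 CPM in 2i, a difference of 5.99. The hormone precursor gene Trh and H19 had the largest positive differences, 9.01 and 7.98. In the other direction, the integrin gene Itga3 went from 60 ± 1.28 to 542 ± 28.1 CPM with JQ1 in serum/LIF and from 23.8 ± 1.71 to 5.97 ± 0.383 CPM in 2i, a difference of -5.13.

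Of 18 naive pluripotency genes 14 had a higher JQ1 effect in 2i and 4 a lower one (camera, Benjamini-Hochberg adjusted p = 2.38e-05, and adjusted p = 0.146 with an estimated correlation), with Nr5a2 at 4.82, Prdm14 at 4.76 and Nr0b1 at 5.52. Core genes had 9 higher and 3 lower of 15 (camera, Benjamini-Hochberg adjusted p = 0.0269, and adjusted p = 0.334 with an estimated correlation), among them Sox2 and Tdgf1 with 1.47 and 5.45. Klf4 and Esrrb differed by 3.16 and 3.48. Mesendoderm genes were higher in 9 of 10 (camera, Benjamini-Hochberg adjusted p = 7.47e-04, and adjusted p = 0.123 with an estimated correlation), such as Foxh1 and Nodal with 2.71 and 1.93. In 2i itself 7 of the 10 fell with JQ1 and 2 rose, without a call for the list (camera, Benjamini-Hochberg adjusted p = 0.0851). The positive difference thus stands beside falls of most members in both media. With vehicle, 8 of the 10 already stood lower in 2i and 2 higher, which can leave less room for a fall. Trophectoderm genes were higher in 9 of 12 (camera, Benjamini-Hochberg adjusted p = 0.0161, and adjusted p = 0.346 with an estimated correlation), with Tfap2c at 1.62 and Gata3 as the exception at -2.92. With a filter of 1.77 CPM the camera, Benjamini-Hochberg adjusted p of that list was 0.0569.

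Germline genes had a higher effect in 2i in 16 of 20 members and a lower one in 2 (camera, Benjamini-Hochberg adjusted p = 3.26e-04, and adjusted p = 0.123 with an estimated correlation). Tex19.1, a repressor of transposons, differed by 3.13, and the germ cell RNA-binding gene Dazl by 3.33. All 5 DNA methylation writers were higher (camera, Benjamini-Hochberg adjusted p = 0.0134, and adjusted p = 0.334 with an estimated correlation), with Dnmt3l, Dnmt3a and Dnmt3b at 2.10, 1.46 and 1.05. The list of TET dioxygenases and base excision was higher in 8 of 9 (camera, Benjamini-Hochberg adjusted p = 0.0343, and adjusted p = 0.165 with an estimated correlation), with Tet1 and Tet2 at 2.85 and 1.28 and Tet3 at -2.11. By edgeR that list had a camera, Benjamini-Hochberg adjusted p of 0.151. Ribosome biogenesis genes were higher in 14 of 22 and lower in 1 (camera, Benjamini-Hochberg adjusted p = 0.0134, and adjusted p = 0.487 with an estimated correlation), with Dkc1, which encodes dyskerin, at 1.5.

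Matrix and adhesion genes had a lower effect in 2i in 17 of 18 members and a higher one in 1 (camera, Benjamini-Hochberg adjusted p = 3.31e-08, and adjusted p = 0.123 with an estimated correlation). Summed feeder fibroblast markers with JQ1 were 0.783 times the vehicle level in serum/LIF and 0.269 times in 2i, so a contribution of such cells stays open. Cald1 and Cyr61 differed by -4.04 and -3.55. The actin-associated genes Flnc and Palld, from outside the list, differed by -4.92 and -4.84, and the sulfatase gene Sulf1 by -5.37. Cholesterol synthesis genes were lower in 13 of 18 and higher in 1 (camera, Benjamini-Hochberg adjusted p = 0.00239, and adjusted p = 0.375 with an estimated correlation), with Ldlr and Fdft1 at -1.49 and -1.40. The p53 list was lower in 12 of 17 and higher in 4 (camera, Benjamini-Hochberg adjusted p = 0.0201, and adjusted p = 0.334 with an estimated correlation), with Mdm2 and Cdkn1a, which encodes p21, at -1.46 and -1.63. Myc, Brd2 and Hexim1 had differences of -2.24, -0.84 and -0.27, and Brd4 one of 0.30.

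In all, 9759 genes differed in their response to JQ1, 5119 with a higher and 4640 with a lower effect in 2i (limma, Benjamini-Hochberg adjusted p below 0.05). At an absolute difference of at least 1, 1370 were higher and 1617 lower. Camera called 12 lists, with the same counts adjusted over the list alone. One of them, the 2-cell-like genes, 6 of 7 lower (camera, Benjamini-Hochberg adjusted p = 0.00102, and adjusted p = 0.123 with an estimated correlation), rests on genes with at most 2 reads in either serum/LIF group apart from Eif1a, and by edgeR it had a camera adjusted p of 0.901 in the other direction. These genes passed the filter only through the 2i vehicle libraries. Their lower value was therefore fixed in advance, and the list test cannot support it. The difference of Enpp2, which had 0.0304 ± 0.0228 and 0.0244 ± 0.0251 CPM in 2i, also depends on the pseudocount. So does that of Osm, with 0 reads in serum/LIF with JQ1. The same holds for other genes with a group below the pseudocount. Among them are Prdm14 and Nr0b1 with JQ1 in serum/LIF and Acta2 with JQ1 in 2i.

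The effect of 2i in vehicle asks how the inhibitors themselves reset the cells. Most of the listed targets of the blocked kinase MEK fell. Spry4, a feedback inhibitor of ERK signaling, fell from 28.7 ± 1.06 to 0.112 ± 0.0436 CPM, the phosphatase gene Dusp6 from 32.5 ± 0.367 to 1.7 ± 0.00592 CPM and the immediate early gene Egr1 from 19.4 ± 1.93 to 0.158 ± 0.0684 CPM. Most of the listed naive genes rose, with Nanog going from 138 ± 6.36 to 539.6 ± 6.7 CPM and Prdm14 from 8.6 ± 0.634 to 37.1 ± 0.84 CPM. The de novo methyltransferase genes Dnmt3a and Dnmt3b fell from 50.5 ± 4.86 to 14.5 ± 0.513 and from 156 ± 13.1 to 48.9 ± 2.05 CPM.

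MEK/ERK target genes fell in 15 of 18 members and rose in 2, with a median log2 fold change of -2.02 (camera, Benjamini-Hochberg adjusted p = 2.36e-04, and adjusted p = 0.365 with an estimated correlation). Naive genes rose in 13 of 18 and fell in 3 (camera, Benjamini-Hochberg adjusted p = 0.0109, and adjusted p = 0.476 with an estimated correlation), with Klf4, Esrrb and Fbxo15 at 1.02, 0.75 and 1.91. Formative and primed genes fell in 14 of 17 and rose in 3 (camera, Benjamini-Hochberg adjusted p = 0.00211, and adjusted p = 0.365 with an estimated correlation), such as the carbonic anhydrase gene Car4 with -5.48. Pou5f1 had a log2 fold change of 0.28, but 0.077 and no call under quantile normalization. Sox2 had 0.12, with -0.071 under quantile normalization, and its call was lost without serum/LIF vehicle replicate 1 or 2 (0.08 and 0.11) or 2i vehicle replicate 1 or 3 (0.09 and 0.10). Wnt targets were divided, 7 up and 6 down of 16 without a call, and the feedback regulator gene Axin2 rose from 4.68 ± 0.0503 to 27.4 ± 1.74 CPM.

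Several lineage lists fell. Feeder fibroblast markers moved the same way without a call for their list, 8 of 12 lower and 3 higher, with a sum of 16.0 to 18.5 CPM in serum/LIF and 6.91 to 7.46 CPM in 2i. Endoderm genes fell in 12 of 15 with 3 that rose (camera, Benjamini-Hochberg adjusted p = 0.0325, and adjusted p = 0.476 with an estimated correlation), mesoderm and smooth muscle genes in 10 of 13 with 3 that rose (camera, Benjamini-Hochberg adjusted p = 0.0319, and adjusted p = 0.326 with an estimated correlation), and trophectoderm genes in 10 of 12 with 2 that rose (camera, Benjamini-Hochberg adjusted p = 0.0148, and adjusted p = 0.476 with an estimated correlation). Examples were Lamb1 with -2.93, Bmp4 with -2.89 and Krt18 with -5.01. The contractile gene Tagln fell from 36.8 ± 3.42 to 0.505 ± 0.225 CPM and the neuronal kinesin gene Kif1a from 52.2 ± 0.502 to 0.273 ± 0.0226 CPM. The 2-cell-like genes rose in all 7 members (camera, Benjamini-Hochberg adjusted p = 0.00211, and adjusted p = 0.326 with an estimated correlation), with Zscan4a at 1 read over the 3 serum/LIF libraries and 1.83 ± 0.279 CPM in 2i. Apart from Eif1a, these members passed the filter only through the 2i vehicle libraries. Their rise was therefore fixed in advance, and the list test cannot support it. Replication genes of G1/S rose in 17 of 20 and fell in 2 (camera, Benjamini-Hochberg adjusted p = 0.00626, and adjusted p = 0.738 with an estimated correlation), with Cdc45 and Cdc6 at 0.90 and 0.81. Cd3g, a T cell receptor subunit gene, had 0 reads in serum/LIF and 9.86 ± 0.622 CPM in 2i, at least 1600-fold higher. The selective autophagy receptor gene Calcoco2 rose from 2.16 ± 0.202 to 159.9 ± 5.83 CPM.

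Tet2 rose from 21 ± 1.59 to 128 ± 30.8 CPM. Tet1 was 221 ± 2.61 and 189 ± 46.7 CPM and did not pass, but fell without 2i vehicle replicate 2, with a log2 fold change of -0.44 and a limma, Benjamini-Hochberg adjusted p of 1.62e-09. Brd2 and Brd4 rose by 0.47 and 0.51, and Brd3 did not pass at 0.02, but was called as lower at -0.13 under quantile normalization. In all, 11135 genes changed, 5718 upward and 5417 downward (limma, Benjamini-Hochberg adjusted p below 0.05), and at an absolute log2 fold change of at least 1, 1380 were higher and 2077 lower. Camera called 8 lists, with the same counts adjusted over the list alone. Under quantile normalization the naive, endoderm, mesoderm, trophectoderm and G1/S lists had camera, Benjamini-Hochberg adjusted p of 0.0532, 0.108, 0.0981, 0.0966 and 0.0981. The endoderm list also lost its call without a filter (camera, Benjamini-Hochberg adjusted p = 0.0689) and with one of 1.77 CPM (adjusted p = 0.17), where the 2-cell-like list could not be tested.

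The effect of 2i in JQ1 compares the media under treatment with JQ1. Nanog stood at 8.4 ± 1.12 CPM in serum/LIF and 633 ± 28 in 2i, a log2 fold change of 6.21 (SE 0.07), and Fgf4 at 1.35 ± 0.162 and 188 ± 5.87 CPM. The adhesion gene Jam2 was higher in 2i, 205 ± 4.18 against 0.749 ± 0.0459 CPM, as was the naive marker Dppa5a, 242 ± 10.4 against 2.28 ± 0.141 CPM. Tagln and Acta2, which encode contractile proteins, were lower: Tagln was 449.7 ± 21 CPM in serum/LIF and 0.61 ± 0.078 in 2i, and Acta2 93.8 ± 7.94 and 0.0232 ± 0.00216 CPM. The tight junction gene Cldn6 was 459 ± 19.4 and 3.81 ± 0.414 CPM.

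Naive genes were higher in 14 of 18 and lower in 3 (camera, Benjamini-Hochberg adjusted p = 7.24e-05, and adjusted p = 0.223 with an estimated correlation), with Prdm14, Nr5a2 and Zfp42, which encodes Rex1, at 6.85, 6.02 and 3.94. Pou5f1, Sox2, Klf4 and Esrrb were higher by 3.86, 1.58, 4.17 and 4.23. Germline genes were higher in 15 of 20 and lower in 1 (camera, Benjamini-Hochberg adjusted p = 0.00231, and adjusted p = 0.223 with an estimated correlation), with Dazl at 5.57. Ribosome biogenesis genes were higher in 17 of 22 and lower in 1 (camera, Benjamini-Hochberg adjusted p = 0.0038, and adjusted p = 0.457 with an estimated correlation), and G1/S genes in 18 of 20 with 1 lower (camera, Benjamini-Hochberg adjusted p = 2.42e-04, and adjusted p = 0.428 with an estimated correlation). Dkc1 and E2f1 had 2.25 and 1.46. Tet1 and Tet2 were higher by 2.61 and 3.86, and Tet3 had -2.12.

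Matrix and adhesion genes were lower in 16 of 18 and higher in 1 (camera, Benjamini-Hochberg adjusted p = 4.18e-07, and adjusted p = 0.199 with an estimated correlation), with Tpm1 at -4.96. Feeder fibroblast markers were also lower, 8 of 12 with 2 higher and without a call for the list, and summed over 18 markers they had between 12.6 and 13.8 CPM in serum/LIF and between 1.79 and 2.08 CPM in 2i. Endoderm genes were lower in 13 of 15 (camera, Benjamini-Hochberg adjusted p = 8.17e-04, and adjusted p = 0.282 with an estimated correlation), mesoderm genes in 10 of 13 (camera, Benjamini-Hochberg adjusted p = 0.00231, and adjusted p = 0.197 with an estimated correlation) and neuroectoderm genes in 8 of 11 (camera, Benjamini-Hochberg adjusted p = 0.0218, and adjusted p = 0.36 with an estimated correlation). Col4a1, Bmp4 and Nes had -4.07, -2.51 and -3.02. MEK/ERK targets were lower in 16 of 18 (camera, Benjamini-Hochberg adjusted p = 2.74e-06, and adjusted p = 0.223 with an estimated correlation), with Dusp4 at -6.19. The p53 list was lower in 12 of 17 (camera, Benjamini-Hochberg adjusted p = 0.00338, and adjusted p = 0.302 with an estimated correlation) and cholesterol synthesis in 17 of 18 (camera, Benjamini-Hochberg adjusted p = 7.24e-05, and adjusted p = 0.315 with an estimated correlation), with Pmaip1, which encodes Noxa, at -2.48 and Lss at -1.28. Myc was lower by 5.00 on the log2 scale.

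In all, 11125 genes differed between the media with JQ1, 6133 higher and 4992 lower in 2i (limma, Benjamini-Hochberg adjusted p below 0.05). At an absolute log2 fold change of at least 1, 1405 were higher and 2272 lower. Camera called 11 lists, and adjusted over the list alone their counts were the same except for 17 MEK/ERK and 13 p53 genes that were lower and 1 cholesterol gene that was higher.

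**Figure D4:**
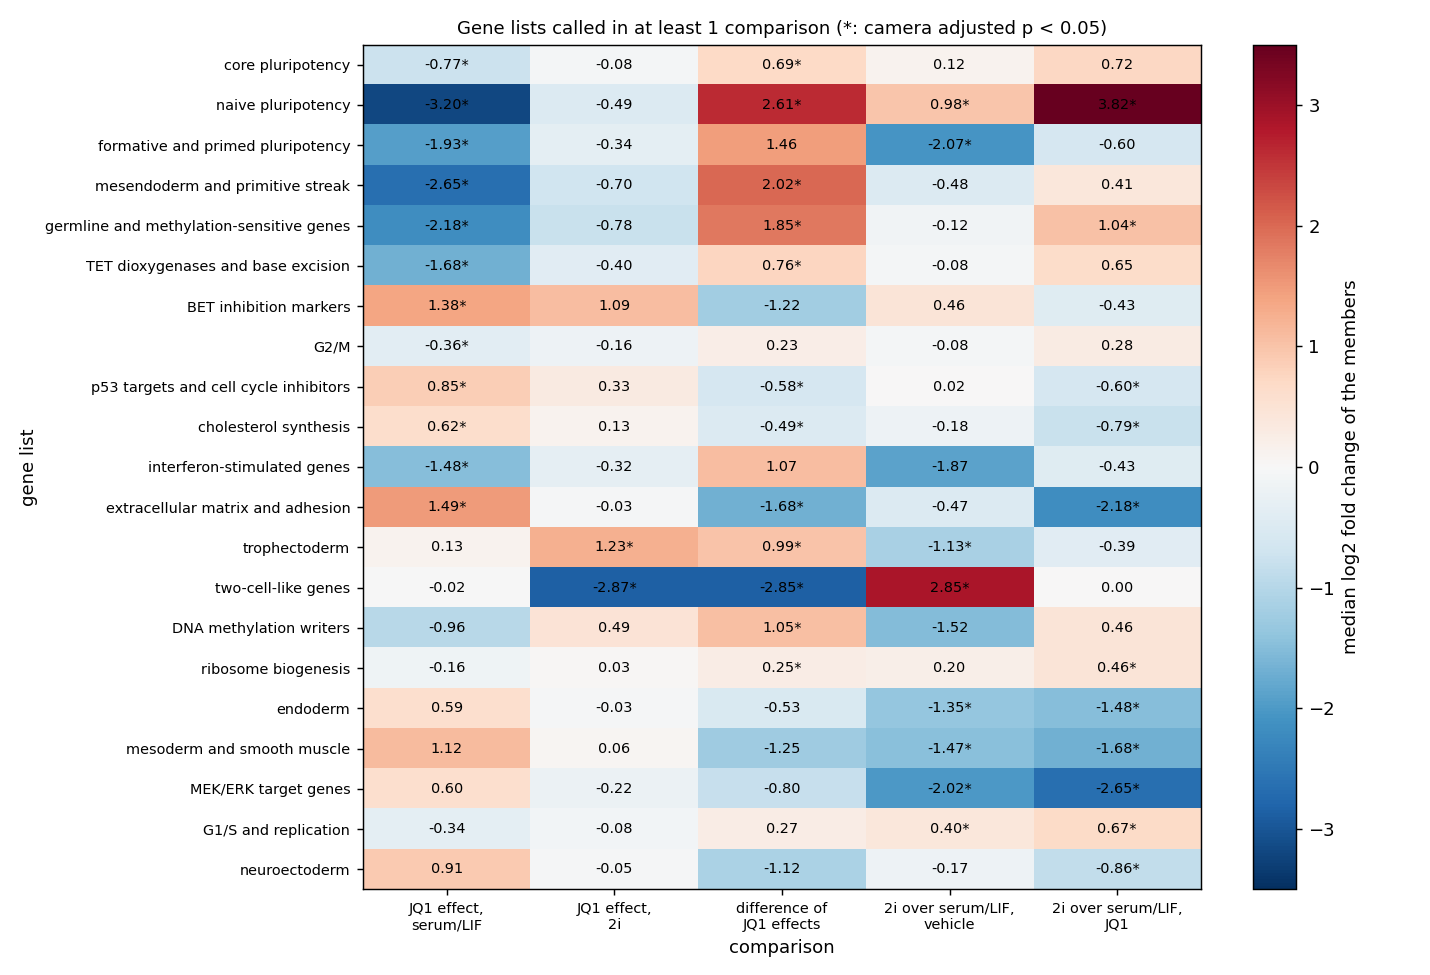
Median log2 fold change of the members of each gene list called in at least 1 of the 5 comparisons (colour and printed value; asterisk, camera adjusted p below 0.05 with the preset correlation). Matrix and adhesion genes stand at 1.49 for JQ1 in serum/LIF; the medians of the 2-cell-like genes depend on the pseudocount, because some groups hold 0 reads.

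The lists below had no call in any of the 5 comparisons. With JQ1 in serum/LIF, 3 of the 4 BET protein genes rose and 0 fell, and 2 of 16 Wnt targets rose and 9 fell. There 8 of 16 LIF/STAT3 targets rose and 8 fell, as did 4 and 4 of 10 MYC family genes, 10 and 5 of 20 lysosome and autophagy genes, 7 and 7 of 17 stress response genes and 5 and 8 of 15 imprinted genes. Of 12 feeder fibroblast markers 2 rose and 8 fell, and without a filter camera called that list downward here and in both comparisons of the media, with Benjamini-Hochberg adjusted p of 0.0396, 0.0164 with vehicle and 0.0171 with JQ1.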

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

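The tests of the macrophage, non-polyadenylated RNA and matrix patterns were chosen after the result was seen, whereas the counts over other splits of the libraries were planned.

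The difference between the JQ1 effects in the media drew attention to the results below, each by a test of that difference. It passed for 9759 genes (limma, Benjamini-Hochberg). Of 100 assignments of the media within each treatment only the real one gave as many, and the highest of the others gave 6441. That highest count points to a structure of the libraries, because assignments that mix the media partly keep the media apart. The assignments also break up the effect of the media itself, so they do not test the difference alone and cannot exclude chance. Since the replicates may be technical, they cannot speak for the spread between cultures either. The other comparisons have too few splits, 10 each, for a share under 0.05. In each of them 1 split, the real one, gave as many genes: 11426 with JQ1 in serum/LIF, 10378 with JQ1 in 2i, 11135 for 2i with vehicle and 11125 for 2i with JQ1, against a highest other count of 0.

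A less negative or more positive effect of JQ1 in 2i, as a difference of log2 fold changes, was found for Trh (9.01), H19 (7.98), Fgf4 (5.99), Enpp2 (5.71), Nr0b1 (5.52), Tdgf1 (5.45), Dppa5a (5.33) and Igf2 (5.24). The same direction held for Prdm14 (4.76), Nanog (4.25), Pou5f1 (3.57), Esrrb (3.48), Klf4 (3.16), Sox2 (1.47) and Brd4 (0.30). Tet1 (2.85), Tet2 (1.28), Dnmt3l (2.10), Dnmt3a (1.46) and Dnmt3b (1.05) also differed that way. The effect was lower in 2i for Sulf1 (-5.37), Itga3 (-5.13), Flnc (-4.92), Palld (-4.84), Bach2 (-4.74), Ctnnd2 (-4.72), Osm (-4.59) and Acta2 (-4.49). It was also lower for Tet3 (-2.11), Myc (-2.24), Brd2 (-0.84) and Hexim1 (-0.27). The value of Osm has no bound behind it, because serum/LIF with JQ1 held 0 reads, and by edgeR it did not pass. The values of Enpp2, Nr0b1, Prdm14 and Acta2 also depend on the pseudocount, because some of their groups lay below it.

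By camera with Benjamini-Hochberg adjustment, the difference was upward for core pluripotency (adjusted p = 0.0269), naive pluripotency (2.38e-05), mesendoderm (7.47e-04), trophectoderm (0.0161), germline genes (3.26e-04), DNA methylation writers (0.0134), TET dioxygenases and base excision (0.0343) and ribosome biogenesis (0.0134). It was downward for 2-cell-like genes (adjusted p = 0.00102), p53 targets (0.0201), cholesterol synthesis (0.00239) and matrix and adhesion (3.31e-08). The 2-cell-like call rests on genes that, apart from Eif1a, had at most 2 reads in any group other than 2i vehicle. They passed the filter only through 2i vehicle, so their lower value was fixed in advance and the call cannot support it. By edgeR that list pointed the other way without a call. With an estimated correlation the smallest adjusted p of these lists was 0.123.

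Macrophage genes stood high in serum/LIF vehicle replicate 2, where Lyz2 had 118 CPM, Ctss 38.5 and Mmp12 26.8. The median log2 ratio to replicates 1 and 3 over 27 other macrophage markers was 3.58, with 7 of them at the filter level in another group as well. Against other blood, vessel or feeder cells, the highest summed ratio of 6 other lineage lists was 1.36, and against depth, the deepest library had 1.12 times the mean of the other 2 libraries of its group. Over 13 macrophage-only genes, replicates 1 and 3 held a median of 2.04% of the level in replicate 2, with an upper quartile 1.58 times the lower, which is consistent with 1 source that also reached them at a low level. Macrophages in the culture and carry-over between libraries stay open, and no biological explanation was tested.

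RNA without a poly(A) tail stood high in 2i vehicle replicate 2, where Rn45s took 56.2% of reads. The median log2 ratio of replication-dependent histone genes to replicates 1 and 3 was 5.52, with 56 of 57 above 1, so incomplete poly(A) selection is a candidate explanation. A first test of genomic DNA, the summed ratio of olfactory receptor genes, was inconclusive at 1.71 and was replaced by the gain per gene. That gain was 0.00022 of the gain per histone gene, which argues against DNA as the cause of the histone rise but leaves a small share of DNA open. A first test of the authors' scaling, the median log2 ratio of all tested genes, gave -0.025, but centring of the libraries would fix that value, and it was replaced. A scaling error moves all genes of a library alike, whereas the median of the histone genes lay 5.54 above that of all tested genes, with quartiles of their log2 ratios at 4.61 and 6.89. Deviations of this library from its group also followed transcript length (Spearman's rho 0.418 over 13320 genes), which was not explained, and no biological explanation was tested. Serum/LIF vehicle replicate 2 also stood above its group, at a far lower level. Rmrp had 2.429 CPM there, against 0.06427 and 0.03058 in serum/LIF vehicle replicates 1 and 3, and Rpph1 2.06 against 0.1357 and 0.1651. The snoRNA genes did not, with a sum of 44.69 CPM against 51.61 and 46.39. Whether RNA passed between these libraries was not tested.

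The listed matrix and adhesion genes rose with JQ1 in serum/LIF and not as a list in 2i. The collagen genes as a family did not rise in serum/LIF, with 12 of 29 higher and 13 lower. The list therefore does not stand for matrix genes as a whole. For more feeder fibroblasts in the JQ1 libraries, their summed markers were 0.783 times the vehicle level in serum/LIF. Of 12 tested markers 2 rose and 8 fell there. JQ1 may change these markers within cells, so their sum cannot decide the number of such cells. In 2i these markers were 0.269 times the vehicle level, so a loss of such cells in 2i may add to the difference between the media and stays open. For scaling between libraries, the largest camera, Benjamini-Hochberg adjusted p of the list under size factors and quantile normalization was 5.48e-05. Camera compares the list with all other genes, and 1 factor per library moves both alike. The outcome under size factors was therefore fixed in advance and cannot decide on scaling. Quantile normalization also evens out the distribution of values, and the list stayed called there. A response of the cells to JQ1 that depends on the medium may stand behind the rise and stays a hypothesis, found and tested on the same data. Other differences between the dishes, such as cell density, were not measured.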

How the results depend on the processing

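The fit without both libraries that stood apart was chosen after the result was seen, and the other alternatives were planned. Counts of changed genes stayed within 1.5 times of the main count under every alternative except the demand for an absolute log2 fold change of at least 1. That left 3775 genes for JQ1 in serum/LIF, 2391 for JQ1 in 2i, 2987 for the difference, 3457 for 2i with vehicle and 3677 for 2i with JQ1, by construction of the limit. None of the scalings can show a shift of all genes alike, so stable counts do not exclude such a shift. Of the values for single genes under the alternatives, 12338 stayed on the same side of the threshold, 14 gained a call, 32 lost one and 11 reversed. Of the values for lists, 2637 stayed, 54 gained a call, 58 lost one and 1 reversed. A change of sign counts as reversed only where the main or the alternative value was called. Values that stayed can therefore include uncalled ones whose sign changed. With a correlation estimated per list, 0 lists were called in each of the 5 comparisons. For JQ1 in 2i the number of called lists was 3 under quantile normalization, 3 without 2i vehicle replicate 2, 3 without both libraries and 5 by edgeR, against 2. For 2i with vehicle it was 3 under quantile normalization, against 8. The cause was not tested for these. With a filter of 1.77 CPM the 2-cell-like list kept only Eif1a and gave no value.

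Under quantile normalization reversed log2 values were -0.022 for Brd4, -0.029 for Brd3 and 0.50 for Brdt with JQ1 in serum/LIF, and 0.21 for Brdt and -0.035 for Nanog with JQ1 in 2i. They were -0.13 for Brd3 and -0.071 for Sox2 for 2i with vehicle, and 0.38 for Brdt and -0.082 for Brd3 for 2i with JQ1. For the difference, Cdx1 reversed to 0.39 by edgeR and 0.42 by DESeq2, and the 2-cell-like list had a camera, Benjamini-Hochberg adjusted p of 0.901 by edgeR in the other direction. The cause was not tested. Pearson's r between the JQ1 effects, 0.539, was 0.505 under quantile normalization, 0.575 and 0.510 with a smaller and a larger pseudocount, 0.524 without a filter and 0.553 with a filter of 1.77 CPM. It ranged from 0.530 to 0.547 on leaving out single libraries. With a term for the replicate number the counts were 11420, 10350, 9721, 11126 and 11123. Libraries with the same number had correlations of -0.122 to 0.149 after removal of group means, and 6 of 12 were most alike with a library of their own number. Depth limits genes near 0 reads, whose folds are bounds, and 2i vehicle replicate 2, where Rn45s took 56.2% of reads.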

Other observations

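The gene families here and their counts without single libraries were chosen after the result was seen, and the tests of the families are camera with Benjamini-Hochberg adjustment over 14 families.

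All 17 tested Hox genes, regulators of body axis identity, rose in 2i with vehicle, at a median log2 fold change of 1.60 (camera, Benjamini-Hochberg adjusted p = 4.06e-06, and adjusted p = 0.00778 with an estimated correlation). Hox genes below the filter were not counted. A gene can pass the filter through the 2i vehicle libraries alone, which favours a rise here and a fall with JQ1 in 2i. All 17 also rose under size factors, under quantile normalization and without both libraries that stood apart. Hoxc12 and Hoxc4 had log2 fold changes of 3.75 and 2.87. With JQ1 in 2i, 12 of the 17 fell and 2 rose (camera, Benjamini-Hochberg adjusted p = 0.0422, and adjusted p = 0.127 with an estimated correlation), but under quantile normalization 10 fell and 6 rose. Keratin genes moved the other way in 2i with vehicle, where 7 of 8 fell at a median of -3.69 (camera, Benjamini-Hochberg adjusted p = 0.00119, and adjusted p = 0.0375 with an estimated correlation). Under quantile normalization 6 fell and 1 rose. Of 29 collagen genes 22 were lower and 2 higher in 2i with JQ1 (camera, Benjamini-Hochberg adjusted p = 9.71e-05, and adjusted p = 0.0198 with an estimated correlation), and under quantile normalization 21 were lower. Feeder fibroblast markers, which include collagens, were lower there too, from a summed 12.6 to 13.8 CPM in serum/LIF to between 1.79 and 2.08 CPM, so whether cells other than stem cells contribute stays open. With JQ1 in serum/LIF the collagens were divided, with 12 that rose and 13 that fell at a median of -0.19 (camera, Benjamini-Hochberg adjusted p = 0.998, and the same with an estimated correlation). Wnt ligand genes fell in 10 of 12 members in 2i with vehicle, with 2 that rose (camera, Benjamini-Hochberg adjusted p = 0.00119, and adjusted p = 0.0551 with an estimated correlation), and in 9 under quantile normalization. Wnt6 and Wnt7b had log2 fold changes of -4.03 and -3.82.

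The Platr transcripts, long noncoding RNAs linked to the pluripotent state, fell with JQ1 in all 9 tested members in serum/LIF, at a median of -2.42 (camera, Benjamini-Hochberg adjusted p = 0.00285, and adjusted p = 0.0672 with an estimated correlation). In 2i 8 of the 9 fell, at a median of -2.27 (camera, Benjamini-Hochberg adjusted p = 0.0082, and adjusted p = 0.102 with an estimated correlation). Under quantile normalization 8 fell in serum/LIF, and in 2i 7 fell and 1 rose. Platr10 had log2 fold changes of -5.99 and -2.79.

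The histone family was not called with JQ1. Of 16 tested members 6 rose and 0 fell in serum/LIF (camera, Benjamini-Hochberg adjusted p = 0.15, and adjusted p = 0.95 with an estimated correlation), and 4 rose and 0 fell in 2i at a median of -0.60 (camera, Benjamini-Hochberg adjusted p = 0.79, and adjusted p = 0.896 with an estimated correlation). Without 2i vehicle replicate 2 alone 12 rose and 0 fell in serum/LIF, and 12 rose and 1 fell in 2i, whereas without serum/LIF vehicle replicate 2 alone 5 and 4 rose and 0 fell in either. Without both, 13 rose and 0 fell in serum/LIF, and 12 rose and 1 fell in 2i. All 69 listed histone genes summed to between 68.4 and 77.9 CPM in serum/LIF with JQ1, against 9.97 to 13.6 CPM with vehicle, and to between 32.7 and 35.1 CPM in 2i with JQ1, against 9.66 and 9.03 CPM in 2i vehicle replicates 1 and 3. Hist1h2bc and Hist3h2a were picked after their values were seen. Without 2i vehicle replicate 2, Hist1h2bc had log2 fold changes of 2.87 in serum/LIF and 2.63 in 2i, and Hist3h2a 4.31 and 2.37. Histone genes share near-identical copies and most of their transcripts lack a poly(A) tail, so the counts depend on how each library was selected.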
